A study of Mus musculus with 25 samples.

How the data were processed

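RNA-seq was deposited for 12 libraries and ATAC-seq for 13 libraries of GFP-sorted mouse retina, 25 in all. Groups follow the labels: assay, stage and sort, giving 6 RNA groups of 2 libraries, 6 ATAC groups of 2 and the single E10 ATAC library. The labels name polyA RNA as the molecule while the protocol names a total RNA kit (TruSeq), and for ATAC-seq a published transposase protocol and a Nextera kit. They do not name the reporter that carries GFP. The processing notes name Bowtie2 and HISAT2 (versions not given in the sources used here), Picard 2.10.7, SAMtools 1.5, featureCounts 1.5.3, bedtools 2.26.0 and the builds mm9 and mm10, without saying which step or assay each served.

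The RNA values deposited by the authors are FPKM, 1 value per gene symbol and library. This unit was inferred from the values, which are not whole and sum to between 383872 and 504845 per library. The program, the annotation and any scaling between libraries behind them are not given in the sources used here. Fragment counts for RNA were not used here, so the depth per library is unknown and no counting interval is given. The deposited ATAC tables hold each a count per feature and library, without normalization: a count over the exons of 23284 genes, in the layout that featureCounts writes, and a count in each of 1424448 windows of 200 bp. Chromosome names and the end of the last window on chromosome 1 (197007908) place both on mm9. Exon counts summed to 1474790 to 15915391 per library and region counts to 11176227 to 94662422. CPM are counts scaled to the library size after TMM. In the figure of 200 bp windows they are scaled to the region total of the library without TMM.

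The window table holds runs of 50 consecutive windows around transcript starts and does not cover the genome. Runs of 50 were summed into 28329 regions of 10 kb, from 27932 of 27965 identifiers, and 7998 windows outside such runs were left out. The planned comparison of genomic 10 kb bins was made on these regions. Start enrichment is the mean count in the central 400 bp over that in the 6 outermost windows, over all regions.

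The statistical plan was fixed before the data were examined. It assumed RNA counts and gave a second choice for normalized values, which was used: log2(FPKM + 1), genes with at least 1 FPKM in at least 2 libraries (14276 of 28446), and limma with an intensity trend in the variance, over all 12 libraries in 6 groups (6 residual degrees of freedom). Contrasts were GFP+ against GFP- at each age, GFP+ cells between ages, GFP- cells between E14 and P2, and the interaction of sort with age from E14 to P2. ATAC counts were fitted with the quasi-likelihood test of edgeR, with TMM scaling and its default filter on low counts (22097 genes and 27902 regions tested). P2 was contrasted with E14 in a fit of all 7 stages (6 residual degrees of freedom), and a second fit took stage rank, 1 to 7, as a number (11 residual degrees of freedom). ATAC SE are the log2 value over the root of the F statistic. P-values were adjusted by Benjamini and Hochberg within each contrast with a threshold of 0.05.

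The 25 gene lists, fixed at the same time, cover progenitor states (RPC core, early RPC, late RPC), the cell cycle (S phase, G2/M), neurogenic genes, Notch and Hedgehog pathways, pan-neuronal genes, retinal cell types (ganglion, horizontal, amacrine, cone, rod, bipolar, Mueller glia), cells that a sort may carry over (microglia, endothelial, erythroid, pigment epithelium, lens, astrocyte, mesenchyme), mitochondrially encoded genes, and immediate early and heat shock genes. They were tested with camera on the log2 values (for ATAC log2 CPM, prior count 2) with a preset correlation of 0.01, adjusted over the lists of a contrast, then with an estimated correlation and with fry. No list was called with an estimated correlation in any contrast. Fry tests whether the genes of a list move, on balance, one way, and does not compare a list with other genes. Members were also adjusted over the list alone.

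The genes named follow a rule fixed with the plan. It takes 23 anchor genes whatever their values. For the sort contrasts, the E14 to P2 contrasts and the ATAC gene contrast it takes the 8 highest and 8 lowest log2 fold changes among called genes whose replicates do not overlap and whose mean reaches 5 FPKM (5 CPM for ATAC) in the higher group, leaving out predicted genes and clones. For the interaction and the ATAC trend it takes 5 each way without the condition on replicates, for each list and contrast up to 4 members with the smallest p, and for regions 4 each way with a mean count of at least 20. Lars2 is given in FPKM because it is listed at 0 in a group. Genes named for their levels in single libraries (Cryaa, Malat1 and the histone share) and the counts on unplaced sequence were chosen after their values were seen. Some of the genes that this rule takes are not reported here.

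RNA and ATAC changes were compared by Pearson's and Spearman's correlation across genes and by Fisher's exact test (two-sided) over genes tested in both. Whether replicate numbers pair libraries was checked before any call was seen, from the correlation across genes of replicate differences between groups. For GFP+ and GFP- cells it was 0.362 at E14, 0.111 at E18 and -0.558 at P2, so libraries were not treated as pairs, and a replicate block was fitted as an alternative. No group holds more than 2 libraries, so other splits of the samples into groups were not counted.

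Alternatives fixed with the plan were a pseudocount of 0.1, no filter on low values, a test against a 1.5-fold change for RNA and a 1.2-fold change for ATAC (a small minimum slope for the trend), only the libraries compared, a replicate block, each replicate left out, and for ATAC size factors of the RLE kind, library size only, loess offsets, DESeq2, a mean count of at least 50 and autosomes only. Added after the data were seen were median-of-ratios and quantile scaling, rescaling of FPKM without 86 histone, mitochondrial and abundant noncoding genes, library quality weights, fits without both E14 libraries numbered 2 and without the 4 E18 libraries, a crossed block at P2, the ATAC trend without E10 and either P2 library, and 10 kb regions in the comparison of RNA with ATAC. RLE factors, DESeq2, the default filter of edgeR and autosomes only need counts or positions that the RNA table lacks and were not run for RNA.

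The pipelines were tested on simulated data with 100 changed genes of each size (200 changed genes or regions for slopes). The limma step called 22% of changes of log2 1 and 72% of log2 2 in the E18 sort contrast, with 3 unchanged genes called, and 23% and 74% in GFP+ cells from E14 to P2, with 10 unchanged genes called. Each gene had the same spread in all simulated RNA libraries. The real groups differed in spread (quality weight 0.102 for E14 GFP- and 3.40 for E18 GFP+), so these rates may not hold for them. The edgeR step called 36% of log2 0.6 and 94% of log2 1 for genes with 13 unchanged genes called, 96% of slopes of 0.2 per step for genes with 4, 43% and 71% for regions with 8, and 82.5% of slopes for regions with 12. Simulated ATAC libraries shared the same profile, without differences in start enrichment such as 22.7 and 12.2 at P2. Changed genes and regions were drawn from those with a mean count above 50. The ATAC rates may thus not hold for the real libraries either. A shifted list was found by camera in each RNA simulation, with 0 other lists called. Noise was drawn for each gene on its own, so the simulations cannot show which lists camera calls in error where genes correlate. Analyses used R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. All deposited sample columns were used.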

Results

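RNA-seq and ATAC-seq, which counts insertions of a transposase into open chromatin, were measured in cells sorted from the retina of CD1 mice by green fluorescent protein (GFP). Per the labels, GFP+ cells are retinal progenitor cells (RPCs) and GFP- cells are post-mitotic retinal cells. RNA was measured at embryonic day 14 (E14), E18 and postnatal day 2 (P2) in 12 libraries, 2 for each sort at each age. ATAC-seq was measured in GFP+ cells only, in 13 libraries at 7 stages: 1 library at E10 (labelled embryonic day 10/11) and 2 each at E12.5, E14, E16.5, E18, P0 and P2. The labels do not say whether replicates are separate animals, so p-values measure only the spread between these samples.

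The RNA libraries summed to between 383872 and 504845 FPKM, and their read depth is unknown. Pearson's r across genes between replicates was 0.993 and 0.989 at E18 (GFP+ and GFP-), 0.988 and 0.98 at P2, and 0.95 and 0.745 at E14. Genes are not independent replicates in these correlations. E14 GFP- replicate 2 was closer to E14 GFP+ replicate 2 (r = 0.978) than to its own partner. Replication-dependent histone genes took 7.73% and 9.57% of FPKM in the E18 GFP+ libraries and 2.61% and 3.15% in the E18 GFP- libraries, against 0.034% to 0.057% in the other 8. Malat1, an abundant nuclear noncoding RNA, stood at 1707 to 3935 FPKM in the 4 E18 libraries and at 79.9 to 134.9 FPKM in the others.

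The ATAC libraries held 1474790 to 15915391 counts over exons and 11176227 to 94662422 over the 10 kb around transcript starts. Counts at transcript starts stood 6.4 times above the flanks at E10, 22.7 and 12.2 times at P2, and 18.5 to 28.6 times at the other stages. E10 and P2 replicate 1 also held 0 counts over the 60 genes that lie only on sequence without a place on a chromosome, where the other 11 libraries held 1633 to 14984 counts.

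**Figure D1:**
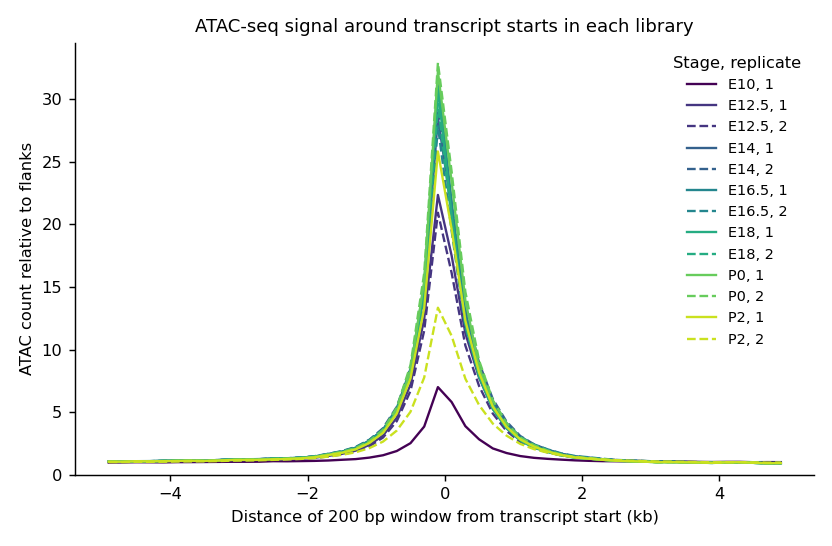
ATAC count in 200 bp windows relative to the flanks (y axis) by distance from the transcript start in kb (x axis), 1 line for each library. Averaged over the central 400 bp, the E10 library reached 6.4 times the flanks and P2 replicate 2 reached 12.2 times, below the 18.5 to 28.6 times of the other libraries.

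Which genes separate progenitors from post-mitotic cells was asked at each age. At E18, 516 of 14276 tested genes differed between the sorts (limma, false discovery rate 0.05), with 161 higher and 355 lower in GFP+ cells. Genes of amacrine interneurons and photoreceptors stood lower in GFP+ cells. Gad1, which makes the inhibitory transmitter GABA, read 0.46 and 0.30 FPKM in GFP+ cells and 28.9 and 33.6 FPKM in GFP- cells, a log2 fold change of -4.55 ± 0.88 (SE, here and for every log2 value; adjusted p = 0.0371). Opn1sw, the short-wave cone opsin, stood at -4.44 ± 0.52 (adjusted p = 0.008). Meis2, a homeobox factor of amacrine cells, stood at -3.52 ± 0.28 and Tfap2b, a transcription factor of amacrine and horizontal cells, at -3.73 ± 0.79. The lowest value was that of Cbln2, a secreted organiser of synapses, at -4.68 ± 0.65. The 8 lowest also held Scn3a, a sodium channel, Kcnip1, Rd3l, Anks1b and Apc2, between -4.38 and -3.80. Pax6, a homeobox factor of progenitors that amacrine cells keep, was lower in GFP+ cells too, at -1.04 ± 0.22 (adjusted p = 0.0439).

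Higher in GFP+ cells at E18 were replication-dependent histone genes, led by Hist1h2ah at 4.08 ± 0.33 (limma, adjusted p = 0.00176). Hist1h2br, Hist2h2aa1, Hist1h3a, Hist1h2bp and Hist1h2bk followed, down to 2.17 ± 0.33 for Hist1h2bk, beside the histone share of FPKM that stood high in all 4 E18 libraries. Prss56, a serine protease tied to eye size, stood at 2.17 ± 0.35 (adjusted p = 0.0242). Lars2, a mitochondrial leucyl-tRNA synthetase, was listed at 0 FPKM in both E18 GFP- libraries and at 5033 and 5031 FPKM in both E18 GFP+ libraries, with 61.2 to 298.9 FPKM in the 8 libraries of the other ages. The 0 may be a failed estimate, so no change is read from it.

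Among the 25 gene lists, 13 differed at E18 by camera with the preset correlation and 0 with an estimated correlation. Only some of the 13 are described here. Of 13 amacrine genes tested, 5 were lower in GFP+ cells over all genes and 9 when adjusted over the list alone (median log2 -2.68, camera adjusted p = 8.04e-07, adjusted p = 0.413 with an estimated correlation). C1ql2, a secreted complement-like protein, stood at -3.07 ± 0.24 and Tfap2a at -2.72 ± 0.52. Of 10 cone genes, 6 were lower over all genes and 9 adjusted over the list alone (median -3.03, camera adjusted p = 1.13e-06, adjusted p = 0.413 with an estimated correlation). They included Gnat2, the cone transducin, at -3.67 ± 0.67, Cngb3, a cone channel subunit, at -3.24 ± 0.59 and Thrb, a thyroid hormone receptor of cones, at -2.45 ± 0.32. Of 17 rod genes, 7 were lower over all genes and 10 adjusted over the list alone (median -1.74, camera adjusted p = 1.13e-06, adjusted p = 0.413 with an estimated correlation). Among them were Rcvrn, a calcium sensor, at -1.74 ± 0.16, Sag, the rod arrestin, at -3.15 ± 0.38 and Aipl1 at -3.14 ± 0.43. The 25 S phase and 25 G2/M genes had medians of 1.53 and 1.85 (camera adjusted p = 1.13e-06 and 6.07e-06, adjusted p = 0.503 for both with an estimated correlation), with 0 members called over all genes or adjusted over the list alone. In mean log2(FPKM + 1), G2/M genes stood at 6.288 and 6.369 in E18 GFP+ and at 4.44 and 4.527 in E18 GFP- libraries. The fit takes 1 spread per gene from all 12 libraries, among them E14 GFP- replicates at 1.683 and 5.185 for G2/M genes. A missing call here thus does not show that the sorts were alike.

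Retinal ganglion cell genes (0 of 16 called either way) had a median of -3.21 at E18 (camera adjusted p = 7.45e-05) and pan-neuronal genes (0 of 16) a median of -2.65 (camera adjusted p = 2.93e-04), both with adjusted p = 0.503 with an estimated correlation. Ganglion cell genes had a mean log2(FPKM + 1) of 1.565 and 1.618 in E18 GFP+ and 4.645 and 4.933 in E18 GFP- libraries. The E14 GFP- replicates, which share in the spread of the fit, stood at 7.104 and 1.839. Late RPC genes had a median of 1.61 (camera adjusted p = 0.00133, adjusted p = 0.503 with an estimated correlation) with 0 of 13 called either way, and Notch genes a median of 1.26 (camera adjusted p = 0.00766, adjusted p = 0.503 with an estimated correlation). The log2 values of the proliferation marker Mki67 (1.86), the cyclin Ccnd1 (1.91), the Notch effector Hes1 (1.94), Sox2 (1.35) and Atoh7 (1.81) did not pass the test. The test was not passed either by Neurog2 (0.82), Fgf15 (2.08), Sfrp2 (1.66), Rlbp1 (1.61), Nfix (1.13), Isl1 (-4.30), Pou4f2 (-2.94) and Nrl (-2.03). A fit of the 4 E18 libraries alone called 7945 genes, against 516 in the fit of all 12, and leaving out any 1 of the 4 gave 23 to 34. With a replicate block 5 of the 516 calls were left. Quantile scaling called 480 genes higher and 464 lower. Rescaling without histone, mitochondrial and abundant noncoding genes, under which the median gene stood at a log2 value of -0.125 (0.00206 as deposited), called 55 higher and 906 lower.

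At P2, 212 genes differed between the sorts (limma), with 16 higher and 196 lower in GFP+ cells. Photoreceptor and amacrine genes were among the lowest. Rcvrn read 0.35 and 0.41 FPKM in GFP+ cells and 27.0 and 26.8 FPKM in GFP- cells (-4.33 ± 0.16, adjusted p = 3.68e-05). Sag stood at -5.15 ± 0.38 (adjusted p = 0.000994) and Opn1sw at -5.26 ± 0.52. The amacrine factor Tfap2a had the lowest value of all at -5.28 ± 0.52 (adjusted p = 0.00276), with 0.47 and 1.73 FPKM in GFP+ and 107 and 55.4 FPKM in GFP- cells. Tfap2b stood at -4.93 ± 0.79 and Gad1 at -4.77 ± 0.88. Crabp1, which binds retinoic acid, stood at -5.12 ± 0.64 and Rd3l at -4.80 ± 0.39.

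The genes higher in GFP+ cells at P2 differed by less: Abcd4 at 1.46 ± 0.24, Tubb4b, a tubulin, at 1.41 ± 0.26, Csrp2 at 1.36 ± 0.23 and Clic1 at 1.33 ± 0.24. Smaller still were Elovl5, a fatty acid elongase, at 1.10 ± 0.15, Klf13, a zinc finger factor (limma, adjusted p = 0.0112), Sorbs2 at 1.04 ± 0.17 and Srd5a1, a steroid reductase, at 1.01 ± 0.19. Of 17 rod genes, 10 were lower in GFP+ cells over all genes and 14 adjusted over the list alone (median -3.28, camera adjusted p = 1.84e-19, adjusted p = 0.211 with an estimated correlation). Gngt1, a rod transducin subunit, stood at -4.68 ± 0.37 and Pde6g, a rod phosphodiesterase subunit, at -4.33 ± 0.49. Of 13 amacrine genes, 7 were lower over all genes and 8 adjusted over the list alone (median -2.07, camera adjusted p = 7.31e-11, adjusted p = 0.211 with an estimated correlation). C1ql2 stood at -4.36 ± 0.24 and Neurod2, a neuronal basic helix-loop-helix factor, at -1.92 ± 0.30. Of 10 cone genes, 3 were lower over all genes and 8 adjusted over the list alone (median -2.65, camera adjusted p = 2.87e-10, adjusted p = 0.286 with an estimated correlation). Arr3, the cone arrestin, stood at -3.19 ± 0.22. G2/M and S phase genes had medians of 1.55 and 1.16 (camera adjusted p = 1.55e-06 for both, adjusted p = 0.497 with an estimated correlation), with 0 of 25 called in each. Mueller glia genes had a median of 1.02 (camera adjusted p = 0.0018, adjusted p = 0.468 with an estimated correlation), with 0 of 12 called over all genes and 2 higher adjusted over the list alone.

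Other anchor genes did not pass the test at P2: Pax6 (-0.94), Sox2 (1.16), Hes1 (1.27), Ccnd1 (1.47), Mki67 (1.51) and Fgf15 (1.77). The same held for Rlbp1 (adjusted p = 0.453), Nfix (0.88), Crx (-1.43), Nrl (-2.79), Isl1 (-1.26) and Otx2 (-0.29). At E18 and P2, 10 genes were higher in GFP+ cells at both ages (0.18 expected, Fisher's exact test, two-sided, p = 1.9e-16). Lower at both were 96 genes (4.87 expected, Fisher's exact test, p = 8.02e-104). These contrasts share an estimate of spread but no library. The P2 count was 2746 from the 4 P2 libraries alone, 35 with a replicate block and 27 without the E18 libraries, and leaving out any 1 of the 4 gave 30 to 163.

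At E14 limma called 0 genes between the sorts, with 2246 at an unadjusted p below 0.05. The log2 values pointed to the same separation without passing the test: Mki67 2.70 ± 0.91, Atoh7, a factor for ganglion cell competence, 2.87 ± 0.92, and Fgf15 3.31 ± 0.91. Further values were Hes1 2.47, Ccnd1 2.91, Neurog2 1.61, Sox2 1.63, Tfap2b -3.82, Isl1 -1.75 and Pou4f2 -1.18. The GFP- replicates lay far apart: Mki67 read 1.69 FPKM in replicate 1 and 31.5 FPKM in replicate 2, against 67.9 and 52.8 FPKM in GFP+ cells. Without E14 GFP- replicate 2, limma called 6870 genes, with replicate 1 of that group assumed to vary like the other groups. Both E14 libraries numbered 2 also held genes of other tissues, such as the lens crystallin Cryaa at 61.2 FPKM (GFP+) and 2676 FPKM (GFP-), listed at 0 in both libraries numbered 1.

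Of the 25 lists, 19 differed between the E14 sorts by camera. G2/M genes had a median of 2.66 (25 of 25 higher adjusted over the list alone, camera adjusted p = 6.89e-13, adjusted p = 0.34 with an estimated correlation). S phase genes had a median of 1.70 (0 of 25 adjusted over the list alone, camera adjusted p = 1.37e-10, adjusted p = 0.34 with an estimated correlation). Neurogenic genes had a median of 1.61 (10 of 15 higher adjusted over the list alone, camera adjusted p = 8.98e-08, adjusted p = 0.337 with an estimated correlation). RPC core genes had one of 2.21 (8 of 14 higher adjusted over the list alone, camera adjusted p = 9.07e-06, adjusted p = 0.337 with an estimated correlation). Notch genes had a median of 1.49 (7 higher and 1 lower of 16, camera adjusted p = 2.43e-05, adjusted p = 0.338 with an estimated correlation). Late RPC genes had one of 1.84 (3 of 13 higher, camera adjusted p = 0.003, adjusted p = 0.361 with an estimated correlation) and early RPC genes one of 1.14 (0 of 13, camera adjusted p = 0.0161, adjusted p = 0.468 with an estimated correlation). Hedgehog genes had one of 1.17 (0 of 11, camera adjusted p = 0.0282, adjusted p = 0.361 with an estimated correlation). Lower in GFP+ cells were ganglion cell genes (median -2.35, 0 of 16, camera adjusted p = 7.73e-05, adjusted p = 0.393 with an estimated correlation). Pan-neuronal genes were lower too (-1.73, 0 of 16, camera adjusted p = 4.59e-04, adjusted p = 0.44 with an estimated correlation). Cone (-0.97, 0 of 10), horizontal (-0.96, 1 of 7 lower) and amacrine genes (-0.94, 4 of 13 lower) had camera adjusted p of 0.003, 0.00573 and 0.0102, with adjusted p = 0.361, 0.337 and 0.361 with an estimated correlation.

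Most of these E14 differences rest wholly or mostly on the libraries numbered 1. In mean log2(FPKM + 1), G2/M genes stood at 6.201 in GFP+ and 1.683 in GFP- replicate 1 but at 5.908 and 5.185 in replicate 2. S phase genes stood at 6.011 and 2.923, then 5.888 and 5.542, and RPC core genes at 7.183 and 3.837, then 6.22 and 5.794. Early RPC genes stood at 5.413 and 3.302, then 6.428 and 6.267, and neurogenic genes at 6.149 and 3.504, then 4.2 and 3.616. Ganglion cell genes had a mean log2(FPKM + 1) of 2.412 in GFP+ and 7.104 in GFP- replicate 1, but 1.682 and 1.839 in replicate 2. Pan-neuronal genes had 3.884 and 7.659 in replicate 1 and 2.856 and 2.879 in replicate 2, and Notch genes 4.754 and 2.119, then 3.976 and 3.895. Late RPC genes had 5.013 and 2.228 in replicate 1, but stood lower in GFP+ than in GFP- cells in replicate 2 (3.616 and 3.942). Hedgehog genes did the same, with 4.207 and 1.89 in replicate 1 and 3.171 and 3.455 in replicate 2.

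Lists of cells from outside the neural retina were lower in E14 GFP+ cells as well. They were erythroid (median -3.48, 4 of 6 lower adjusted over the list alone, camera adjusted p = 9.09e-04), and pigment epithelium (-2.23, 3 of 5 lower, adjusted p = 0.0095). They were also microglia (-0.49, 0 of 4, adjusted p = 0.017), astrocyte (-1.04, 0 of 4, adjusted p = 0.0202) and lens genes (-2.38, 0 of 8, adjusted p = 0.0352). Their adjusted p with an estimated correlation was 0.292, 0.337, 0.337, 0.337 and 0.468, in the same order. The lens difference rests on the libraries numbered 2, with a mean log2(FPKM + 1) of 3.146 in GFP+ and 7.813 in GFP- cells, against 0.02825 and 0.06902 in those numbered 1. The pigment epithelium difference rests mostly on the libraries numbered 2 as well (1.189 and 4.082, against 0.2209 and 1.27 in those numbered 1). Mitochondrially encoded genes, high in all 12 libraries, were lower in GFP+ cells too (-0.65, 0 of 10, camera adjusted p = 0.00702, adjusted p = 0.338 with an estimated correlation). Erythroid genes included Hba-a1, an alpha globin, at 1225 and 48.8 FPKM in GFP- and 4.34 and 6.59 FPKM in GFP+ cells. Erythroid genes stood lower in GFP+ cells at E18 too (mean log2(FPKM + 1) of 0.8707 and 0.9124, against 3.188 and 2.89). The same held at P2 (0.1941 and 0.2023, against 1.727 and 1.847). Endothelial genes went the other way at E18 (3.662 and 3.634 in GFP+ and 2.821 and 3.049 in GFP- cells). Camera did not call 6 lists at E14, among them immediate early and heat shock (median 0.53, adjusted p = 0.0688) and endothelial (0.50, 0.0708). The others were Mueller glia (0.30, 0.0978), rod (-0.17, 0.113), bipolar (-0.38, 0.113) and mesenchyme (-0.9999, 0.18). Mean mesenchyme log2(FPKM + 1) was 1.59 (GFP+) and 4.381 (GFP-) in replicate 2, but 0.9498 and 0.5117 in replicate 1.

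**Figure D2:**
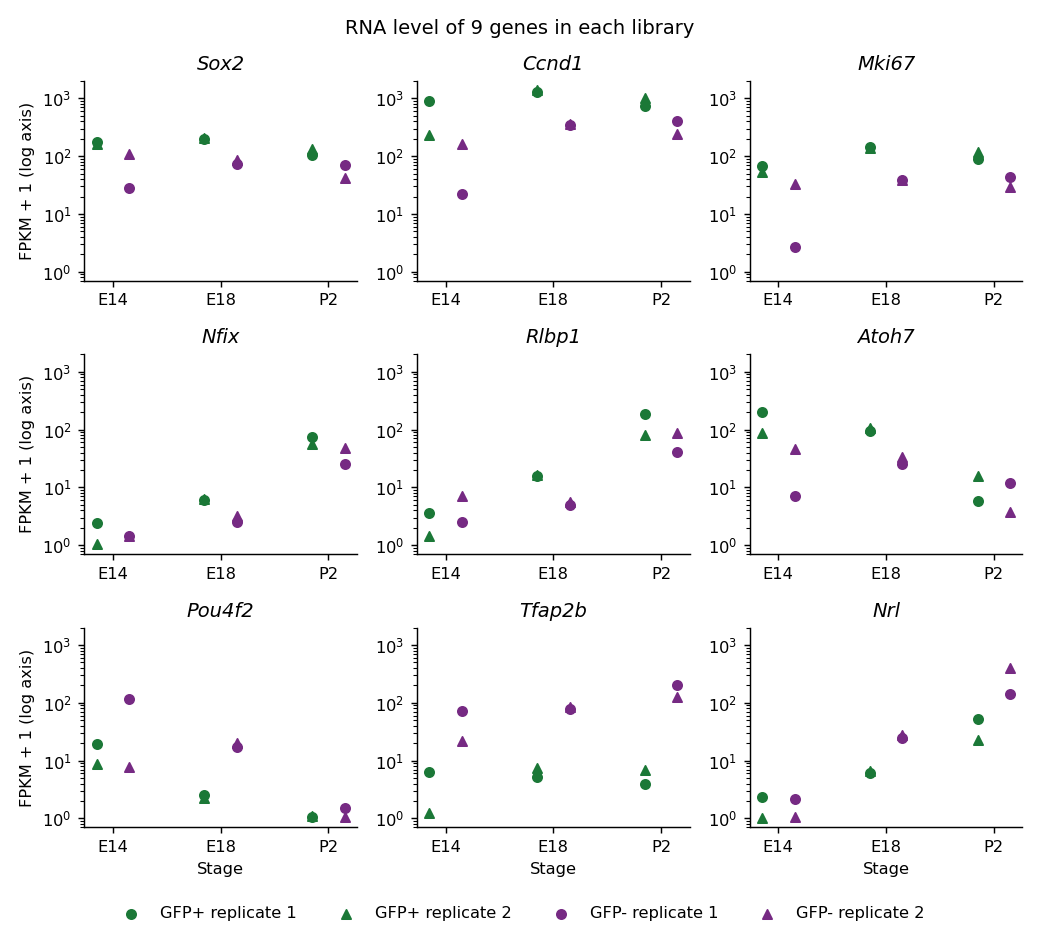
FPKM + 1 (log axis) of single RNA libraries for 9 named genes at E14, E18 and P2 (x axis), with GFP+ in green, GFP- in purple, replicate 1 as circles and replicate 2 as triangles. Mki67 stood at 1.69 and 31.5 FPKM in the E14 GFP- replicates, while Rlbp1 in GFP+ cells went from 2.66 and 0.41 FPKM at E14 to 187.7 and 79.5 FPKM at P2.

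How progenitors change with age was asked in GFP+ cells from E14 to P2. Limma called 164 genes, 133 higher and 31 lower at P2. Some genes of late progenitors and Mueller glia were among those higher at P2. Rlbp1, a retinoid-binding protein of Mueller glia, rose by 5.76 ± 0.66 (log2, adjusted p = 0.00847). Nfix, a nuclear factor I gene, rose by 5.33 ± 0.43 (adjusted p = 0.00204), from 1.43 and 0.07 FPKM to 72.2 and 55.8 FPKM. Its relative Nfib rose by 3.03 ± 0.39 (adjusted p = 0.0131). The rod factors Nr2e3 and Nrl rose by 4.56 ± 0.54 and 4.48 ± 0.63, and Otx2, a homeobox factor of photoreceptors and bipolar cells, by 2.49 ± 0.32. Hkdc1, a hexokinase, Epha8, an ephrin receptor, Entpd2, an ectonucleotidase, and Prss22 rose by 5.04, 4.92, 4.57 and 4.24.

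Lower at P2 in GFP+ cells were Dlx1, a homeobox gene, at -2.33 ± 0.42 (limma, adjusted p = 0.0444), Slc6a17 at -2.26 ± 0.41, Thbs3 at -2.21 ± 0.35 and Stbd1 at -1.93 ± 0.35. Lower too were Cdh4, R-cadherin, at -1.81 ± 0.28, Eya2, of the eyes absent family, at -1.63 ± 0.26 and Pycr1, of proline synthesis, at -1.62 ± 0.26. Atoh7 (-3.77 ± 0.92, adjusted p = 0.105), Sfrp2, a Wnt inhibitor (-4.53 ± 1.64), Fgf15 (-2.22), Lin28b, an RNA-binding protein (-2.32), and Pou4f2 (-3.62) did not pass the test. Neither did Crx (3.86 ± 1.11) and Nfia (2.82 ± 0.70). Nor did Sox2 (-0.50), Hes1 (-0.55), Pax6 (-1.09), Ccnd1 (0.92), Mki67 (0.74), Neurog2 (0.02), Isl1 (-1.97), Onecut1 (-2.11) and Tfap2b (0.88).

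Of 17 rod genes, 5 rose in GFP+ cells over all genes and 14 adjusted over the list alone (median 1.84, camera adjusted p = 2.02e-11, adjusted p = 0.388 with an estimated correlation). Sag (2.85 ± 0.38) and Rom1 (2.72 ± 0.45) were among them. Of 13 late RPC genes, 4 rose over all genes and 8 adjusted over the list alone (median 2.82, camera adjusted p = 1.55e-07, adjusted p = 0.388 with an estimated correlation). Car2, a carbonic anhydrase, rose by 4.19 ± 0.74. Early RPC genes had a median of -1.79 (0 of 13 called over all genes, 2 lower adjusted over the list alone, camera adjusted p = 1.91e-05, adjusted p = 0.466 with an estimated correlation). Mueller glia genes rose in 3 of 12 cases over all genes and 4 adjusted over the list alone (median 1.47, camera adjusted p = 4.52e-04, adjusted p = 0.388 with an estimated correlation). The potassium channel gene Kcnj10 rose by 3.23 ± 0.26. Of 15 neurogenic genes, 1 rose over all genes, and 7 rose and 2 fell adjusted over the list alone (median 1.25, camera adjusted p = 6.44e-04, adjusted p = 0.524 with an estimated correlation). This rise rests on E14 replicate 2, where the neurogenic mean of log2(FPKM + 1) was 4.2, against 6.149 in E14 replicate 1 and 6.18 and 6.458 at P2. Of 16 Notch genes, 1 rose over all genes, the Notch target Hey2 (3.45 ± 0.41), and 2 adjusted over the list alone (median 0.89, camera adjusted p = 0.00604, adjusted p = 0.524 with an estimated correlation). This rise rests mostly on E14 replicate 2 as well, with a Notch mean of 3.976, against 4.754 in E14 replicate 1 and 4.973 and 5.179 at P2.

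Of 4 endothelial genes, Kdr, a receptor for vascular endothelial growth factor, rose over all genes (2.49 ± 0.42), and 3 rose adjusted over the list alone (median 1.54, camera adjusted p = 4.52e-04, adjusted p = 0.388 with an estimated correlation). S phase and G2/M genes had medians of -0.45 and 0.11 in GFP+ cells and were not called by camera (adjusted p = 0.066 and 0.689). The 164 calls were 0 with only the 4 GFP+ libraries of these ages (2834 at an unadjusted p below 0.05, limma) and 0 without the E18 libraries (1300 at an unadjusted p below 0.05). Leaving out 1 library gave 15 and 37 calls without P2 replicate 1 and 2, and 470 and 46 without E14 replicate 1 and 2.

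Set against E18, the same GFP+ cells differed in 1203 genes from E14 (623 higher and 580 lower at E18, limma) and in 1139 genes from P2 (638 higher and 501 lower at P2). The E18 libraries also carried the high histone and Malat1 levels, so age was not told apart from a difference between libraries in these steps. E14 GFP+ replicate 1 lay closer to P2 GFP+ (r = 0.944 and 0.966) than to E18 GFP+ (0.915 and 0.912). Replicate 2 did too (0.89 and 0.91, against 0.864 and 0.862). Rlbp1 rose in each step, by 2.82 ± 0.66 to E18 (adjusted p = 0.0351) and by 2.94 ± 0.66 from E18 to P2 (adjusted p = 0.0316), as did Nfix, by 1.94 ± 0.43 and 3.39 ± 0.43. Nfib rose to E18 by 1.96 ± 0.39, and Otx2 (1.78 ± 0.32) and Sag (2.37 ± 0.38) rose from E18 to P2. Atoh7 differed by -0.38 to E18 and by -3.40 ± 0.92 from E18 to P2 (adjusted p = 0.0612), neither past the test. The eye homeobox gene Six3 fell to E18 (-2.85 ± 0.34) and rose to P2 (3.22 ± 0.34), with 13.6 and 15.1 FPKM at E18, 140.9 and 84.7 FPKM at E14 and 137.1 and 147.3 FPKM at P2.

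Mitochondrially encoded genes moved the same way as Six3. Of 10, 7 were lower at E18 than at E14 over all genes and 8 adjusted over the list alone (median -2.03, camera adjusted p = 1.7e-05, adjusted p = 0.538 with an estimated correlation). From E18 to P2, 8 were higher over all genes and 9 adjusted over the list alone (median 2.88, camera adjusted p = 5.34e-09, adjusted p = 0.19 with an estimated correlation). The subunit mt-Atp6 fell by 5.06 ± 0.66 and mt-Co3 by 3.95 ± 0.65 to E18. These lists moved with the E18 libraries, which also carried the high histone and Malat1 levels. Late RPC genes rose to E18 in 5 of 13 cases over all genes and 8 adjusted over the list alone (median 1.94, camera adjusted p = 0.00952, adjusted p = 0.908 with an estimated correlation). This rise rests mostly on E14 replicate 2, with a late RPC mean of log2(FPKM + 1) of 3.616. The mean was 5.013 in E14 replicate 1 and 5.8 and 5.885 at E18. Rod genes rose from E18 to P2 in 3 of 17 cases over all genes and 5 adjusted over the list alone (median 1.36, camera adjusted p = 1.7e-05, adjusted p = 0.974 with an estimated correlation). Rescaling without histone, mitochondrial and abundant noncoding genes called 805 genes higher and 352 lower at P2 than at E18. Fitted alone, the libraries of GFP+ cells at E18 and P2 gave 5311 calls, and leaving out any 1 of them in the fit of all libraries gave 350 to 408.

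In GFP- cells, 976 genes differed between E14 and P2 (limma), 648 higher and 328 lower at P2. The fit shares its spread between all groups, while the E14 GFP- replicates lay further apart (r = 0.745) than those of any other group. The SE and p-values of this contrast may thus be too small, and with quality weights 2 genes were called. Rod genes rose, Nr2e3 by 8.30 ± 0.54 (adjusted p = 0.000532), Sag by 7.73 ± 0.38 (adjusted p = 0.000144) and Nrl by 7.29 ± 0.63. Prph2, of the outer segment disc rim, Pdc, phosducin, and Samd7, a photoreceptor repressor, rose by 6.61, 6.22 and 5.89. Fabp7, a fatty acid-binding protein of glia and progenitors, rose by 6.34 ± 1.12. Lower at P2 were some ganglion cell genes, among them the RNA-binding protein Rbpms (-5.03 ± 1.04, adjusted p = 0.028) and the transcription factor Pou4f2 (-4.56 ± 1.02, adjusted p = 0.0365). Falls were also seen for the growth factor Igf1, the T-box factor Tbx20, the retinoic acid-binding Crabp2, the actin-severing Gsn, Fblim1 and the neuropeptide Gal, between -3.92 and -3.63. The fall of Rbpms and Pou4f2 went with the spread of the E14 replicates, at 306.3 and 17.5 FPKM for Rbpms and 114.3 and 6.61 FPKM for Pou4f2.

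Of 17 rod genes, 15 rose in GFP- cells over all genes and 16 adjusted over the list alone (median 5.22, camera adjusted p = 5.62e-21, adjusted p = 0.249 with an estimated correlation). Rcvrn rose by 4.73 ± 0.16. Of 15 neurogenic genes, 8 rose over all genes and 13 adjusted over the list alone (median 2.40, camera adjusted p = 9.08e-08, adjusted p = 0.287 with an estimated correlation). Neurod1 rose by 3.97 ± 0.59 and Otx2 by 3.30 ± 0.32. Of 13 amacrine genes, 6 rose over all genes and 7 adjusted over the list alone (median 2.15, camera adjusted p = 4.52e-07, adjusted p = 0.287 with an estimated correlation). C1ql2 rose by 4.52 ± 0.24. Of 10 cone genes, 4 rose over all genes and 7 adjusted over the list alone (median 2.35, camera adjusted p = 1.76e-05, adjusted p = 0.32 with an estimated correlation). Opn1sw rose by 5.70 ± 0.52. Late RPC genes rose in 6 of 13 cases over all genes and 9 adjusted over the list alone (median 2.69, camera adjusted p = 9.34e-07, adjusted p = 0.287 with an estimated correlation). RPC core genes rose too, in 2 of 14 cases over all genes and 4 adjusted over the list alone (median 1.77, camera adjusted p = 0.00624, adjusted p = 0.52 with an estimated correlation). Their mean log2(FPKM + 1) in GFP- cells was 3.837 and 5.794 at E14 and 6.765 and 6.492 at P2. In P2 GFP+ cells it was 7.31 and 7.446, so the P2 GFP- libraries carried much RNA of progenitor genes. Notch and G2/M genes had medians of 1.955 and 1.202 (camera adjusted p = 3.46e-04 and 0.00363, adjusted p = 0.446 and 0.696 with an estimated correlation). The G2/M rise rests on E14 replicate 1, with a mean of 1.683 there, 5.185 in E14 replicate 2, 4.44 and 4.527 at E18 and 5.038 and 4.329 at P2. All GFP- libraries but this E14 replicate thus carried much RNA of G2/M genes, though the labels name GFP- cells post-mitotic. The Notch rise rests mostly on E14 replicate 1 too, at 2.119, against 3.895 in E14 replicate 2 and 4.541 and 4.336 at P2. Nfix rose by 4.62 ± 0.43, Sox8 by 4.52 ± 0.73 and Rlbp1, a Mueller glia gene, by 3.82 ± 0.66.

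Further lists moved in GFP- cells. Of 16 ganglion cell genes, 3 fell over all genes and 4 adjusted over the list alone (median -2.40, camera adjusted p = 7.82e-05, adjusted p = 0.52 with an estimated correlation). This fall rests on E14 replicate 1, where the ganglion cell mean of log2(FPKM + 1) was 7.104, against 1.839 in E14 replicate 2 and 2.038 and 1.633 at P2. Immediate early and heat shock genes rose in 4 of 13 cases over all genes and 8 adjusted over the list alone (median 1.52, camera adjusted p = 1.06e-04, adjusted p = 0.287 with an estimated correlation). Ier3 rose by 1.94 ± 0.21 and the chaperone Hspa1b by 3.23 ± 0.67. Anchor genes that did not pass the test in GFP- cells were Ccnd1 (2.36), Mki67 (1.94), Atoh7 (-1.43), Isl1 (-2.46), Lin28b (-2.83), Nfia (2.35), Sfrp2 (-3.48) and Tfap2b (1.99). The 976 calls were 5282 without E14 GFP- replicate 2, 4853 without E14 GFP- replicate 1, 606 without P2 GFP- replicate 1 and 129 without P2 GFP- replicate 2. They were 0 with only the 4 libraries compared (1334 at an unadjusted p below 0.05, limma). Rescaling without histone, mitochondrial and abundant noncoding genes, under which the median gene stood at 0.186 (0.0316 as deposited), called 1205 higher and 261 lower.

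Whether the change from E14 to P2 differed between the sorts was tested as an interaction, and limma called 21 genes, 2 higher and 19 lower in the change of GFP+ cells minus that of GFP- cells. The E14 GFP- libraries enter this contrast as well, so its SE may also be too small. The 19 held photoreceptor and amacrine genes that rose more in GFP- cells. Rcvrn differed by -4.26 ± 0.23 (adjusted p = 0.000719), C1ql2 by -4.28 ± 0.33 (adjusted p = 0.00644), Sag by -4.89 ± 0.53, Rd3l by -4.33 ± 0.55 and Gngt1 by -4.20 ± 0.52. Gsn (2.93 ± 0.40) and Anxa6, a calcium-dependent membrane-binding protein (2.52 ± 0.32), went the other way. None of the 23 anchor genes was called. Of 17 rod genes, 3 were called lower over all genes and 13 adjusted over the list alone (median -2.99, camera adjusted p = 7.99e-26, adjusted p = 0.22 with an estimated correlation). Amacrine genes followed with 1 of 13 over all genes and 4 adjusted over the list alone (median -1.49, camera adjusted p = 9.85e-09, adjusted p = 0.241 with an estimated correlation). Of 10 cone genes, Arr3 was called over all genes (-3.09 ± 0.31) and 2 adjusted over the list alone (median -1.21, camera adjusted p = 3.1e-07, adjusted p = 0.358 with an estimated correlation). The 21 calls were 0 with only the libraries of E14 and P2 (418 at an unadjusted p below 0.05, limma), 0 with a replicate block (715), 0 with a pseudocount of 0.1 (596) and 1 with quality weights. They were 874 and 2947 without E14 GFP- replicate 1 and 2, and 1 to 44 without 1 of the other 6 libraries.

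**Figure D3:**
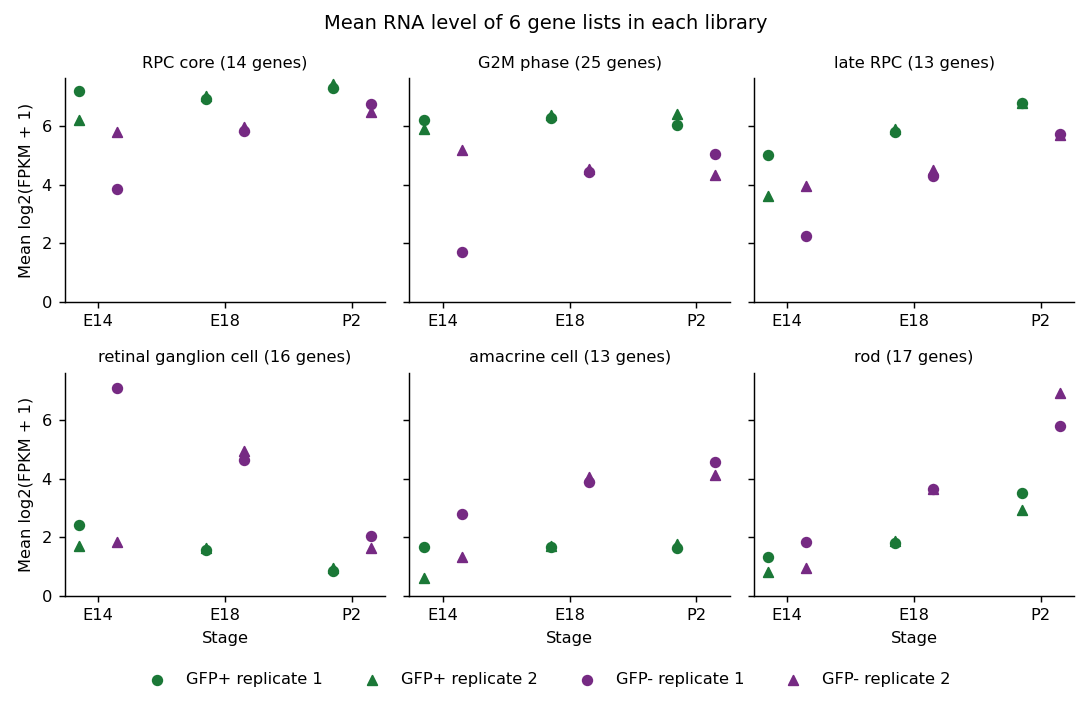
Mean of log2(FPKM + 1) over the tested genes of gene lists (y axis) in single RNA libraries at E14, E18 and P2, 2 points for each of GFP+ and GFP-. Rod genes (17 genes) rose by a median of 5.22 in GFP- and 1.84 in GFP+ cells from E14 to P2 in the limma fit.

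Chromatin of GFP+ cells was compared between E14 and P2 from counts over exons. Of 22097 genes tested, 5762 differed (edgeR, false discovery rate 0.05), 2443 higher and 3319 lower at P2. Rlbp1 (mm9 chromosome 7, 86519756 to 86531913) rose by 2.48 ± 0.16 (log2, adjusted p = 8e-11). Crx, a photoreceptor homeobox gene (chromosome 7, 16451296 to 16465304), rose by 1.48 ± 0.22 (adjusted p = 2.2e-05), Nfix (chromosome 8, 87231498 to 87324239) by 1.43 ± 0.14 and Otx2 by 0.82 ± 0.17. Atoh7 (chromosome 10, 62562904 to 62563353) fell by 0.76 ± 0.14, Sfrp2 by 0.81 ± 0.16 and Tfap2b by 0.75 ± 0.15. Isl1, a homeobox gene of ganglion and amacrine cells, fell by 0.55 ± 0.13, Onecut1 by 0.46 ± 0.14 and Pou4f2 by 0.40 ± 0.13. Nfib fell by 0.85 ± 0.15 in these counts (chromosome 4, 81936077 to 82151212), from a mean of 177.2 to 98.4 CPM, while its RNA rose. Pax6 (-0.11), Sox2 (-0.24), Hes1 (-0.01), Ccnd1 (0.38), Mki67 (0.19), Neurog2 (-0.20), Nrl (0.35), Nfia (0.34), Fgf15 (-0.12) and Lin28b (-0.22) did not pass the test.

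Besides these anchors, the 8 highest values among genes whose replicates do not overlap belonged to Snx9, the microRNA genes Mir5109 and Mir802, Aym1 (3.17 ± 0.21), Omg, a myelin glycoprotein (3.16 ± 0.24), Ptgds, a prostaglandin synthase (2.95 ± 0.26), and the olfactory receptor genes Olfr91 and Olfr1107. Snx9 rests on 1 P2 library: it held 56.6 CPM in P2 replicate 1, 1.09 CPM in P2 replicate 2, 37.9 CPM at E10 and at most 0.85 CPM elsewhere. Olfr1107 rests mostly on the same library, with 31.6 CPM there, 5.25 CPM in P2 replicate 2, 3.10 and 2.06 CPM at E14 and 14.0 CPM at E10. The 8 lowest included Kcnj13, a potassium channel of the pigment epithelium (-2.71 ± 0.27), Cbln4 (-2.56 ± 0.18) and Ifi47, an interferon-induced gene (-2.69 ± 0.20). With them were the vomeronasal receptor genes Vmn1r25 (-3.73 ± 0.31) and Vmn1r30 (-2.84 ± 0.43), and Vamp7. Vamp7 lies on the unplaced sequence where P2 replicate 1 held 0 counts.

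Of 18 rod genes, 10 rose over all genes and 12 adjusted over the list alone (median 0.89, camera adjusted p = 8e-06, adjusted p = 0.322 with an estimated correlation). Among them were Sag (1.34 ± 0.24), Prdm1, a repressor in photoreceptor precursors (0.77 ± 0.14), and Gnat1, the rod transducin (0.68 ± 0.13). Endothelial genes rose in 8 of 11 cases (median 0.72, camera adjusted p = 0.00767, adjusted p = 0.604 with an estimated correlation), with Emcn at 1.69. Of 25 S phase genes, 7 fell and 1 rose over all genes (median -0.27, camera adjusted p = 0.0179, adjusted p = 0.604 with an estimated correlation). Fen1, a flap endonuclease, stood at -0.59 and Mcm5, of the replicative helicase, at -0.55. Lens genes rose in 4 of 12 cases and fell in 1 over all genes, and rose in 7 and fell in 1 adjusted over the list alone (median 1.10, camera adjusted p = 0.0379, adjusted p = 0.604 with an estimated correlation). With loess offsets the S phase and lens lists were no longer called (camera adjusted p = 0.362 for both), and 6 lists not called otherwise were called up. These were RPC core, Notch, late RPC, amacrine, Mueller glia and neurogenic genes (camera adjusted p of 1.34e-07, 6.3e-05, 0.00141, 0.00539, 0.00842 and 0.025). Late RPC genes went both ways, with 4 higher, such as Crym (2.25 ± 0.18), and 4 lower (median 0.24). The ligand Shh fell by 1.66 ± 0.22 among Hedgehog genes, of which 4 rose and 5 fell. Scaling to library size alone, under which the median gene stood at 0.224 (0.026 with TMM), called 4466 genes higher and 2339 lower. Leaving out a library gave 13202 calls without P2 replicate 1 and 2820 and 2402 without E14 replicate 1 and 2, and a fit of the P2 and E14 libraries alone gave 2319.

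Over all 7 stages, 1239 genes followed stage rank (edgeR), 618 rising and 621 falling. Rlbp1 rose by 0.34 ± 0.06 (log2 per stage step), though not steadily. Its means in stage order were 29.8, 16.5, 11.4, 23.6, 33.1, 50.4 and 63.4 CPM. The first is from the E10 library, where start enrichment was 6.4 and counts around this start showed no clear peak. The 200 bp window at the start (86531713 to 86531912) held 1.104 CPM at E10, as did that at 86529513 to 86529712. Nfix rose by 0.31 ± 0.04, Ccnd1 by 0.26 ± 0.06 and Otx2 by 0.15 ± 0.04. The 5 steepest rises were those of Aym1 (0.75 ± 0.10), Mir802 (0.73 ± 0.08), Mir9-3, a neural microRNA (0.55 ± 0.07), Ttr, transthyretin (0.51 ± 0.07), and Bccip (0.48 ± 0.07). The steepest falls were those of Mir5119, Nlrp1c-ps, Sirpb1a, Olfr724 and Mir5112. Of these, Mir5119, Nlrp1c-ps and Mir5112 rest on the single E10 library, at 30.2, 15.8 and 11.3 CPM there, against at most 1.47, 0.75 and 0.73 CPM in any other library. Olfr724 held 7.67 CPM at E10 and at most 2.24 CPM elsewhere, and Sirpb1a 6.77 CPM at E10 and 5.14 and 5.98 CPM at E12.5.

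RPC core genes rose with stage in 5 of 14 cases over all genes and 12 adjusted over the list alone (median 0.15 per step, camera adjusted p = 5.76e-07, adjusted p = 0.303 with an estimated correlation). The same list was not called between E14 and P2 (median 0.07, camera adjusted p = 0.26). Its trend goes with a step after E12.5, where start enrichment was lower (6.4 at E10 and 18.5 and 19.9 at E12.5, against 23.7 to 28.6 from E14 to P0). Means in stage order were 61.4, 76.3, 150.3, 138.5, 137.3, 144.2 and 126.6 CPM for Sox2 and 71.3, 72.5, 136.8, 154.6, 164.4, 139.3 and 135.5 CPM for Hes1, and signal was not told apart from stage. Neurogenic genes rose in 5 cases and in 8 adjusted over the list alone (median 0.13, camera adjusted p = 2.14e-05, adjusted p = 0.136 with an estimated correlation). Late RPC genes rose in 4 and 7 (median 0.12, camera adjusted p = 3.97e-05, adjusted p = 0.121 with an estimated correlation). Notch genes rose in 5 and 8, with 1 falling adjusted over the list alone (median 0.12, camera adjusted p = 0.001055, adjusted p = 0.16 with an estimated correlation). Amacrine genes rose in 4 cases (median 0.09, camera adjusted p = 0.00338, adjusted p = 0.122 with an estimated correlation). S phase genes went up by stage rank, against their direction between E14 and P2, with 1 of 25 called over all genes and 4 adjusted over the list alone (median 0.06, camera adjusted p = 0.001055, adjusted p = 0.609 with an estimated correlation). G2/M genes rose in 2 of 25 cases and 3 adjusted over the list alone (median 0.07, camera adjusted p = 8.09e-04, adjusted p = 0.609 with an estimated correlation). Mesenchyme and lens genes had medians of -0.12 (camera adjusted p = 0.026 for both, adjusted p = 0.609 with an estimated correlation). With loess offsets the S phase, G2/M and lens lists were no longer called by stage rank (camera adjusted p = 0.174, 0.0837 and 0.602). RPC core, neurogenic and late RPC genes stayed called up (camera adjusted p = 3.28e-07, 1.21e-04 and 0.0084), as did Notch and amacrine genes (0.043 for both). Mesenchyme genes stayed called down (camera adjusted p = 0.0426). Rod genes (up, camera adjusted p = 0.0426) and pan-neuronal genes (down, 0.043) became called. Bipolar and microglia genes (down) and Mueller glia and immediate early and heat shock genes (up) had camera adjusted p between 0.0263 and 0.0306, with adjusted p = 0.609 with an estimated correlation. None of these 4 lists was called with loess offsets (camera adjusted p of 0.119, 0.602, 0.528 and 0.0568, in the same order). The 1239 calls were 9361 without P2 replicate 2, with all 1239 among them, and 289 without P2 replicate 1. Without E10 and P2 replicate 1, the libraries with 0 counts on unplaced sequence, 1104 genes were called, 578 of the 1239 among them.

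**Figure D4:**
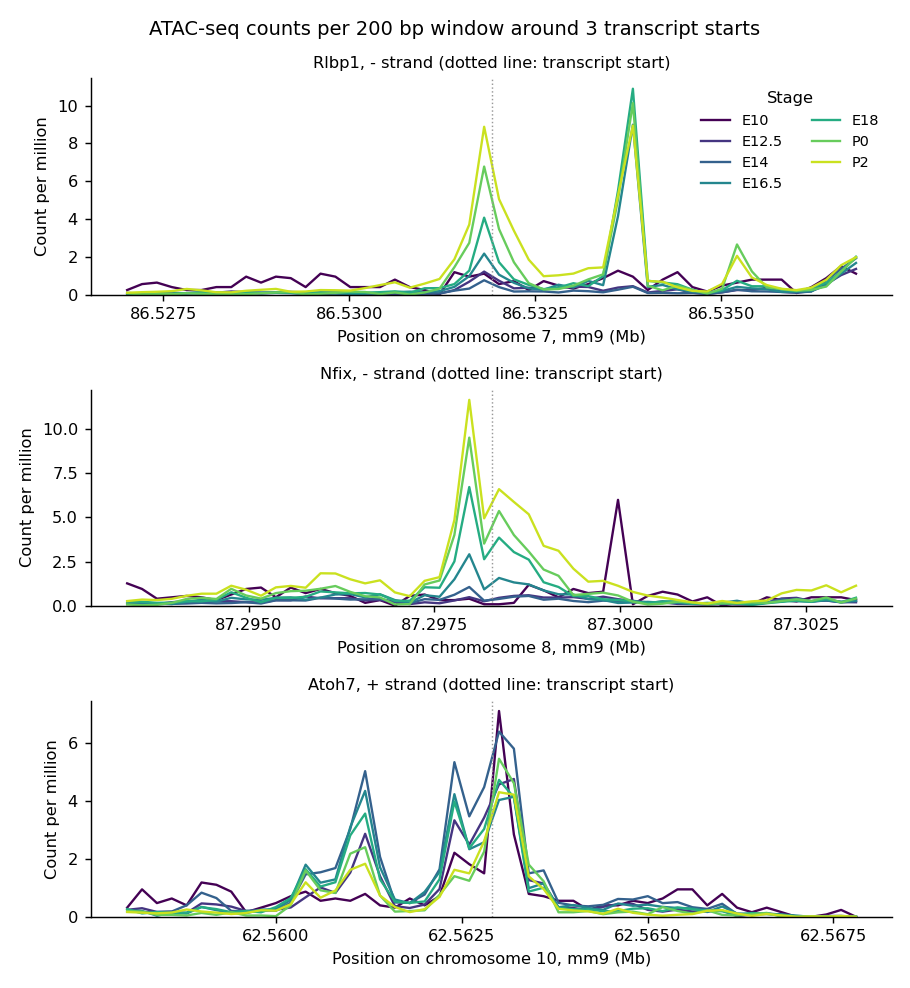
Mean ATAC CPM in 200 bp windows (y axis) along mm9 coordinates (x axis) in 10 kb around starts of Rlbp1, Nfix and Atoh7, 1 line for each of 7 stages. The whole Rlbp1 region held 10.4 and 10.8 CPM at E14 and 63.3 and 54.5 CPM at P2, and that of Atoh7 held 57.7 and 60.9 CPM at E14 and 28.3 and 27.0 CPM at P2.

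The same question was put to 10 kb regions centred on transcript starts, of which 27902 were tested. They overlap one another and are not independent. Between E14 and P2, 8699 differed (edgeR), 4109 higher and 4590 lower at P2, and over the 7 stages 1452 rose and 1370 fell. The Rlbp1 region (chromosome 7, 86526913 to 86536912) rose by 2.48 ± 0.13 (adjusted p = 1.55e-28). Of 2 Nfix starts, the region at 87293268 to 87303267 on chromosome 8 rose by 2.44 ± 0.13, from 13.6 and 14.7 to 81.0 and 72.6 CPM, and the other by 1.16 ± 0.12. A Nfia start (chromosome 4, 97243634 to 97253633) rose by 1.74 ± 0.17 while another stood at 0.17 and did not pass. Regions at Nrl (0.99 ± 0.13) and both Crx starts (1.29 ± 0.36 at 16452734 and 0.66 ± 0.12 at 16460304) rose. Those at Atoh7 (-1.10 ± 0.13), Isl1 (-0.77 ± 0.16), Lin28b (-0.74 ± 0.12), Sfrp2 (-0.58 ± 0.17) and Onecut1 (-0.42 ± 0.13) fell. Some regions did not follow the exon counts. The 3 Otx2 regions (-0.15, -0.05 and -0.03), the Nfib region (0.21), both Tfap2b regions (-0.16 and -0.22) and the Pou4f2 region (-0.20) did not pass the test, while their exon counts did.

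By stage rank, regions at Nfix (87293268, 0.41 ± 0.05 per step), Rlbp1 (0.37 ± 0.06), Nfia (0.43 ± 0.07), Crx (16460304, 0.21 ± 0.03), Nfib (0.20 ± 0.05), Sox2 (0.19 ± 0.05) and Ccnd1 (0.16 ± 0.05) rose, beside a region at Pou2f1, an octamer-binding factor (0.62 ± 0.08). The Crx start at 16452734 (0.04, adjusted p = 0.744) and the other Nfix start (0.14, adjusted p = 0.0726) did not pass by stage rank. The lowest values in both tests were those of the Gm17644 region (chromosome 1, 12652644 to 12662643), at -3.42 ± 0.19 between E14 and P2 and -0.72 ± 0.10 per step. The highest between E14 and P2 were at Atg7, Disc1 and C87414 and rest on P2 replicate 1. The Atg7 region held 18.0 CPM there, 0.055 CPM in P2 replicate 2, 20.3 CPM at E10 and 0 in the other 10 libraries. The Disc1 region held 16.1, 0.055, 18.8 and 0 CPM. Scaling to library size alone, under which the median region stood at 0.18 (0.0235 with TMM), called 5743 regions higher and 3895 lower. Without P2 replicate 1, 21100 regions were called between P2 and E14, and without P2 replicate 2, 16982 by stage rank.

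Changes of RNA and of ATAC counts from E14 to P2 in GFP+ cells were compared over 12391 genes tested in both, which share no library. Across genes, which are not independent replicates, Pearson's r was 0.291 and Spearman's rho 0.206. Of 125 genes with higher RNA and 1095 with higher ATAC counts, 67 were shared (11.1 expected, Fisher's exact test, two-sided, p = 5.79e-38), among them Rlbp1, Nfix and Otx2 (the last by exon counts only). Of 26 genes with lower RNA and 2630 with lower ATAC counts, 7 were shared (5.52 expected, Fisher's exact test, p = 0.473). Higher RNA met lower ATAC counts in 7 genes (26.5 expected), among them Nfib, whose 10 kb region did not pass the test. With 10 kb regions in place of exons, r was 0.337 and 76 genes were higher in both (11.2 expected). Leaving out 1 RNA library gave 8 and 19 genes higher in both without P2 replicate 1 and 2, and 130 and 26 without E14 replicate 1 and 2. The overlap of lower genes changed its call, and the cause was not tested: 52 were shared without RNA E14 replicate 1 (29.7 expected, Fisher's exact test, p = 1.52e-05) and 166 without both E14 libraries numbered 2 (100.2 expected, Fisher's exact test, p = 1.38e-12).

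**Figure D5:**
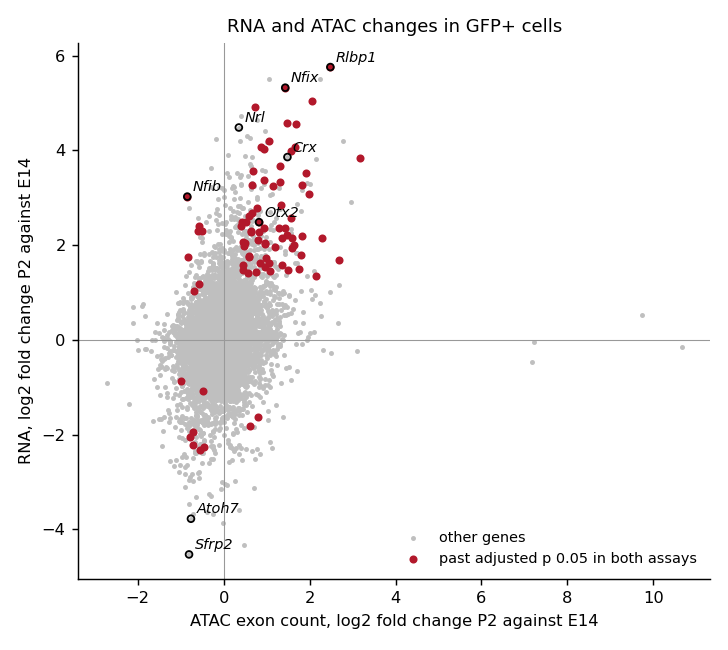
Log2 fold change of RNA (y axis) against that of ATAC exon counts (x axis) between P2 and E14 in GFP+ cells, 1 point for each of 12391 genes, with genes called in both in red. Rlbp1 stood at 5.76 in RNA and 2.48 in ATAC, and Nfib at 3.03 and -0.85, while the few points beyond 6 on the x axis have nearly all their P2 counts in replicate 1.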

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

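The tests of exchanged labels, of an earlier age and of S phase were chosen after the values they measure had been seen. The test of RNA without poly(A) tails was rewritten around replacement histones after a first list of such RNAs proved mostly absent, with the rise of the other histone genes already seen.

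For 7 named genes the change from E14 to P2 differed between the sorts by the interaction test of limma. These calls are fragile, since 0 of the 21 in the interaction were left with a replicate block (715 at an unadjusted p below 0.05, limma) or a pseudocount of 0.1 (596). Sag differed by -4.89 ± 0.53 (adjusted p = 0.0267), having risen by 2.85 in GFP+ and 7.73 in GFP- cells. C1ql2 differed by -4.28 ± 0.33 (adjusted p = 0.00644; 0.25 and 4.52), Rcvrn by -4.26 ± 0.23 (adjusted p = 0.000719; 0.47 and 4.73), Rd3l by -4.33 ± 0.55 (adjusted p = 0.0328; 0.19 and 4.52) and Gngt1 by -4.20 ± 0.52 (adjusted p = 0.0328; 0.91 and 5.11). Gsn differed by 2.93 ± 0.40 (adjusted p = 0.0499), with -0.77 in GFP+ and -3.70 in GFP- cells, where it read 15.4 and 16.1 FPKM at E14 and 0.47 and 0.13 FPKM at P2. Anxa6 differed by 2.52 ± 0.32 (adjusted p = 0.0328), with 1.13 in GFP+ and -1.39 in GFP- cells.

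The E14 RNA libraries numbered 2 stood apart from those numbered 1, and E14 GFP- replicate 2 lay closer to E14 GFP+ replicate 2 (r = 0.978 across genes) than to its partner (r = 0.745). An exchange of labels between both libraries numbered 2 is argued against: RPC core genes had a median log2 value of 0.43 in GFP+ over GFP- among them, with 13 of 14 above 0. A simple mixture of GFP+ replicate 2 with cells like GFP- replicate 1 is argued against too, since 11 progenitor genes gave a GFP+ share of 0.64 (quartiles 0.57 to 0.78) and 32 neuronal genes one of 1.0 (quartiles 0.99 to 1.0), a difference of -0.36. The test modelled only these parts, so it cannot decide about GFP+ cells mixed with cells of another kind. An earlier age of the libraries numbered 2 remains a candidate explanation: in GFP+ cells early RPC genes stood at a median of 1.03 in replicate 2 over replicate 1 (10 of 13 above 0), late RPC genes at -1.24 (11 of 13 below 0) and neurogenic genes at -1.51 (15 of 15 below 0). RNA from outside the neural retina was present in the libraries numbered 2. Lens genes had a mean log2(FPKM + 1) of 3.146 (GFP+) and 7.813 (GFP-) there, against 0.02825 and 0.06902 in those numbered 1. The lens crystallin Cryaa read 2676 FPKM and the embryonic globin Hbb-y 190.5 FPKM in GFP- replicate 2. How much of the difference between replicates such RNA accounts for stays open, and no label gives litters or days within a group.

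The 4 E18 RNA libraries carried far more histone RNA. More cells in S phase is argued against as the whole cause, since S phase genes differed at E18 from the mean of E14 and P2 by a median of 0.49 in GFP+ and 0.39 in GFP- cells, while 66 histone genes differed by 7.61 and 6.0. RNA without poly(A) tails kept in the E18 libraries is a candidate explanation: 11 replacement histone genes, whose transcripts carry such tails, differed by 0.17 in GFP+ and 0.03 in GFP- cells. The labels describe all 12 libraries alike, and any difference in preparation would coincide with stage here.

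ATAC P2 replicate 2 had a start enrichment of 12.2 against 22.7 in P2 replicate 1, and a difference in signal to background may have given calls between P2 and E14. With loess offsets, which remove trends with abundance, 76.4% of the 5762 genes called (4400) stayed called in the same direction. The bounds set beforehand were under 20% for such a difference as the cause and at least 80% against it, so this value decides neither way. No biological explanation was tested, since both libraries share stage and sort.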

How the results depend on the processing

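The scalings, weights and fits without chosen libraries that processing lists as added were chosen after the data were seen; the others were fixed beforehand. Most alternatives changed 1 choice, while DESeq2 changed scaling, dispersion, test and filter together and some fits left out several libraries. Of 285 recomputed values for 26 results, 138 were within 1.5 times of the reported one and 147 moved, and of 7462 recomputed values for named genes, regions and lists 6155 kept their direction and their side of the threshold, 864 lost the call, 427 gained it and 16 reversed. Causes were not tested beyond what fewer libraries, fewer genes or a stricter threshold set by construction.

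Calls between GFP+ and GFP- at E14 (0 reported) were 9 without a filter, 3 with median-of-ratios scaling and 7038 without both E14 libraries numbered 2. The cause was not tested. At E18 (516) they were 7945 from the groups compared, 38 against a 1.5-fold change, 5 with a replicate block, 143 with a pseudocount of 0.1, 970 without a filter, 944 with quantile scaling, 961 rescaled, 8254 with quality weights and 7197 without both E14 libraries numbered 2. The cause was not tested. At P2 (212) they were 2746 from the groups compared, 59 against a 1.5-fold change, 35 with a block, 340 rescaled, 3884 with quality weights, 4708 without both E14 libraries numbered 2 and 27 without the E18 libraries (205 with a block crossed at P2). The cause was not tested, but the E14 GFP- libraries, whose quality weight was 0.102 against 3.40 for E18 GFP+, share their spread with all groups in the reported fit.

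Calls in GFP+ P2 against E14 (164) were 0 from the groups compared, 42 against a 1.5-fold change, 92 with a block, 1042 with quality weights, 1169 without both E14 libraries numbered 2 and 0 without the E18 libraries. In E18 against E14 (1203) they were 313 against a 1.5-fold change, 2778 with quality weights and 2721 without both E14 libraries numbered 2. In P2 against E18 (1139) they were 5311 from the groups compared, 305 against a 1.5-fold change, 6202 with quality weights and 4930 without both E14 libraries numbered 2. In GFP- P2 against E14 (976) they were 0 from the groups compared, 244 against a 1.5-fold change, 1466 rescaled, 2 with quality weights, 6532 without both E14 libraries numbered 2 and 89 without the E18 libraries. The interaction (21) gave 0 from the groups compared, 2 against a 1.5-fold change, 0 with a block (715 at an unadjusted p below 0.05, limma), 0 with a pseudocount of 0.1 (596), 10 with quantile scaling, 1 with quality weights, 0 with the crossed block (965), 3505 without both E14 libraries numbered 2 and 0 without the E18 libraries (418). The cause was not tested. Without both E14 libraries numbered 2, all reported calls of the E18, P2, GFP+ P2 against E14, P2 against E18, GFP- and interaction contrasts stayed called, and 1186 of 1203 in E18 against E14. That fit assumes that the 1 remaining library of each E14 group varies like the others.

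Leaving out 1 library gave, as lowest and highest, 0 and 6870 calls for the E14 sort (6870 without E14 GFP- replicate 2), 23 and 34 at E18, 30 and 163 at P2 (30 without P2 GFP+ replicate 2), 15 and 470 in GFP+ P2 against E14 (15 without P2 replicate 1, 470 without E14 replicate 1), 378 and 1231 in E18 against E14 (378 without E18 replicate 1), 350 and 408 in P2 against E18, 129 and 5282 in GFP- (129 without P2 replicate 2, 5282 without E14 replicate 2) and 1 and 2947 for the interaction (2947 without E14 GFP- replicate 2). For ATAC it gave 2402 and 13202 genes in P2 against E14 (13202 without P2 replicate 1), 289 and 9361 by stage rank (289 without P2 replicate 1, 9361 without P2 replicate 2), 3878 and 21100 regions (21100 without P2 replicate 1) and 1371 and 16982 by stage rank (16982 without P2 replicate 2). For RNA against ATAC it gave r of 0.2405 and 0.2918, rho of 0.1747 and 0.2192, 8 and 130 genes higher in both and 0 and 52 lower in both (52 without RNA E14 replicate 1, 29.7 expected, Fisher's exact test, p = 1.52e-05).

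ATAC genes in P2 against E14 (5762) were 3116 against a 1.2-fold change and 2319 from the groups compared. By stage rank (1239) they were 230 against a minimum slope, 797 with a block, 2471 with DESeq2, 6314 without E10 and P2 library 2 and 1104 without E10 and P2 library 1 (578 of the 1239 among them). Regions in P2 against E14 (8699) were 3947 against a 1.2-fold change and 2490 from the groups compared, and by stage rank (2822) 912 against a minimum slope, 12223 without E10 and P2 library 2 and 2257 without E10 and P2 library 1 (1433 of the 2822 among them). On autosomes only, which leaves out unplaced sequence, 5731 genes were called in P2 against E14. Over the 83 genes called in RNA and in ATAC, r was 0.549 and rho 0.399, and RNA without both E14 libraries numbered 2 gave 213 genes higher and 166 lower in both (166 against 100.2 expected, Fisher's exact test, p = 1.38e-12). The cause was not tested.

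With an estimated correlation 0 lists were called in each of the 10 contrasts. Fry called 2 lists at E14 (19 by camera), 7 at E18 (13), 4 at P2 (13), 7 in GFP+ P2 against E14 (11), 2 in E18 against E14 (4), 1 in P2 against E18 (4; 2 with a block), 1 in the interaction (12), 9 in ATAC P2 against E14 (4; 8 with loess offsets) and 5 by ATAC stage rank (13; 8 with loess offsets). The cause was not tested.

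Some signs reversed, and the cause was not tested. In GFP- P2 against E14, leaving out 1 library took Hes1 from -1.598 (without E14 GFP- replicate 1) to 2.898 (without E14 GFP- replicate 2) and Sox2 from -0.9985 to 0.9509 in the same order, and Sox2 stood at 0.9509 without both E14 libraries numbered 2. Without both E14 libraries numbered 2 the interaction of Nfia was -1.36, and list directions turned for amacrine genes in GFP+ P2 against E14 (adjusted p = 0.9985), early RPC and lens genes in GFP- P2 against E14 (0.9696 and 0.6796), and Hedgehog and pan-neuronal genes in the interaction (0.0015 and 9.04e-07). With loess offsets ATAC exon counts gave 0.32 for Pax6, 0.32 for Hes1 and 0.25 for Neurog2, and regions 0.39 for Hes1, 0.22 for Neurog2 and 0.22 for Otx2. The Hes1 region stood between -0.3871 (without P2 replicate 1) and 0.2231 (without P2 replicate 2).

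Depth limits the E10 and P0 ATAC libraries most, with 1804412 exon counts at E10 and 2922609 and 1474790 at P0, and RNA depth is unknown.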

Other observations

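Genes in this part were chosen after their values were seen, except where a list named them.

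Levels of some cell type genes in GFP- cells differed between the ages, without a test of their order or of cell composition. Rcvrn was listed at or near 0 FPKM at E14, at 2.51 and 2.60 FPKM at E18 and at 27.0 and 26.8 FPKM at P2. Opn1sw read 74.6 and 82.3 FPKM in GFP- cells at E18 and 133.7 and 67.5 FPKM at P2. Of the rod genes, Nr2e3 read 22.2 and 26.4 FPKM at E18 and 197 and 613.5 FPKM at P2, and Nrl 23.2 and 26.6 FPKM at E18 and 141.7 and 398.1 FPKM at P2. The ganglion cell gene Rbpms went the other way, with 34.5 and 42.0 FPKM at E18 and 1.93 and 0.80 FPKM at P2. In GFP+ cells Nr2e3 read 36.5 and 14.7 FPKM at P2 and Sag 6.95 and 5.83 FPKM, below the GFP- cells of the same age. The fatty acid-binding gene Fabp7 read 435.8 and 214.3 FPKM in GFP+ and 251.6 and 448.8 FPKM in GFP- cells at P2, against 23.6 and 0.82 FPKM in GFP+ cells at E14.

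In chromatin, the mean exon count of Nfib was highest at E14 (177.2 CPM) and 89.3 to 123.1 CPM at the other 6 stages. Atoh7 had its highest mean at E14 too (61.6 CPM), with 28.4 CPM at E10 and 36.1 CPM at P2. Crx held means of 21.7, 7.69, 9.18, 12.8, 15.4, 31.6 and 25.9 CPM in stage order, the first from the E10 library with its start enrichment of 6.4.

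E10 and P2 replicate 1 had 0 counts in all 7748 windows on unplaced sequence, where P2 replicate 2 held 39498 and E14 replicate 2 held 138322. Of the 60 genes on such sequence alone, 27 were tested and 8 were called lower at P2 than at E14 (edgeR). A further 16 genes had counts in E10 and P2 replicate 1 and 0 counts in the other 11 libraries, among them Tsnax and Rsph3a, and 7 of the 8 tested were called higher at P2. How the alignment of these libraries differed is not given in the sources used here, and comparisons at these genes set libraries with counts against libraries without.

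In RNA, Gm26917 read 2157 to 3207 FPKM in the 4 E18 libraries and 10.8 to 529.4 FPKM in the others. Over genes low in both libraries, the most common ratio to E14 GFP+ replicate 1 was 2.46 to 3.73 in E18 libraries and 0.5 to 1.15 in the others, and depths were not recovered from it. The embryonic globin Hbb-y read 31.3 FPKM in E14 GFP+ replicate 2 and 190.5 FPKM in E14 GFP- replicate 2, against at most 1.57 in the other 10 libraries. Sfrp2 read 1459 and 1043 FPKM in the E14 libraries numbered 2 (GFP+ and GFP-) and 237.6 and 14.7 FPKM in those numbered 1.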
